A study of Mus musculus with 9 samples.

How the data were processed

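RNA sequencing was analysed in 9 libraries of mouse male germ cells. The cells carried an Id4-EGFP reporter transgene and were taken from testes at postnatal day 6, per the labels. ID4-EGFP+ cells were sorted as a whole (3 libraries, all ID4-EGFP+), or sorted again by antibody staining for the surface tetraspanin TSPAN8 into a strongly stained fraction (3 libraries, TSPAN8-high) and a weakly stained fraction (3 libraries, TSPAN8-low). Per the labels each fraction was 1/3 of the stained cells, so both together do not make up the whole. Per the labels' protocols, cDNA was made with the SMART-Seq v4 kit, which primes on poly(A) tails, and libraries with Nextera XT, followed by paired-end sequencing. This kit does not mark strand, so reads of a gene and its antisense partner were not separated. Sorts by other surface proteins named in the protocol were not analysed here. Each group's 3 libraries are separate preparations per the labels; whether they came from separate litters is not given in the sources used here, so p-values measure the spread between these preparations.

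The authors deposited Cufflinks FPKM values (fragments scaled by transcript length and by mapped fragments per library) for each library, and these were the values tested. Per the submitters' processing notes, the tools were FastQC, TopHat2 2.0.12, Bowtie2 2.2.3.0 and Cufflinks, and the genome build was mm9; the Cufflinks version and the gene annotation are not given in the sources used here. The authors also deposited a table of normalized values, treated here as signal and used only as an alternative. In each library the log10 of these values was a straight line of log10 FPKM, with slopes of 0.973 to 1.02 and with 1e-04 put in place of 0. A further deposited table, the log10 of the normalized one, was not used here. Library columns were matched to samples by the letters and the number in the column names, which correspond to the population and the sample number in the titles. A mouse annotation of a later build (GENCODE M21) served for transcript length and GC content only, so no coordinates are given; 11044 of the tested genes (99.1%) had both values.

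The table held 23813 entries. The 262 symbols on more than 1 entry (768 entries) were left out because their values could not be assigned to 1 gene, and 27 entries showed a date in place of a symbol. Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested (11142 genes). Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend, two-sided) on log2(FPKM + 1), in one fit over the 9 libraries with 3 groups and no further scaling. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Means ± SD are of FPKM. Cufflinks estimates for small RNAs and for members of near-identical gene families are uncertain, since reads can be split between copies.

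The 4 contrasts were TSPAN8-high against TSPAN8-low, each fraction against all ID4-EGFP+, and the mean of both fractions against all ID4-EGFP+. The comparisons, the gene lists, the rule for named genes and the first set of alternatives below were chosen before the data were examined. The 23 lists held 344 genes, none on more than 1 list: stem cell, undifferentiated, progenitor, differentiating, meiosis, growth factor response, retinoic acid, BMP and Id, cell cycle, glycolysis, respiratory chain, DNA methylation, tetraspanins, Eph and ephrin, adhesion and matrix, immediate early, and markers of Sertoli, Leydig, peritubular myoid, interstitial, endothelial, leukocyte and red blood cells. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 21 lists that had at least 2 tested members. Camera was also run with an estimated correlation, with and without the replicate block described below, and no list then passed in any of the 4 contrasts. It was not run this way under the other alternatives, so list calls seen only there have no p of that kind. Named genes were Tspan8, Id4, Epha2 and Pvr; the 10 genes with the largest rise and the 10 with the largest fall, TSPAN8-high against TSPAN8-low, among those past the threshold whose 3 values did not overlap; up to 4 tested members of each list with the smallest p; and up to 5 genes in each direction from the other contrasts. The result of 1 gene that this rule takes is not reported here. Python 3.11.15 and matplotlib 3.10.9 were used for tables and plots.

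Libraries of the 3 groups share replicate numbers in the labels. The 9 pairs of libraries with the same number in different groups deviated together from their group means (r of 0.26 to 0.48 across genes), while the 18 pairs with other numbers had r of -0.46 to 0.28. The numbers were therefore taken to pair the samples, as a pattern in the data. A second fit had the number as a block, and its values are given beside a result where they change a call or move a reported count by more than 1.5 times.

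Depth per library is unknown in absolute terms, since FPKM keeps no read totals. From the step between low values of the same gene, the relative depth of the libraries was 0.856 to 1.05 of that of all ID4-EGFP+ replicate 1, with the TSPAN8-low libraries at 0.856, 0.945 and 0.889. On data simulated at the spread of these libraries, the fit without the block called 100% of genes changed by 2 on the log2 scale between TSPAN8-high and TSPAN8-low, 59.7% of those changed by 1 and 1.49% of those changed by 0.5. With the block these shares were 100%, 77.6% and 20.9%. Of the 10942 genes left unchanged, 0 were called without the block and 3 with it. A change under 2-fold was therefore often not detectable with 3 libraries per group. Apart from the replicate effect, the simulated noise was independent between genes. The real libraries also deviated along GC content (Spearman's rho of -0.38 to 0.53 per library), so the count of false calls may be higher in them.

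The alternatives were a pseudocount of 0.1, no filter, the authors' normalized table, a common median, quantile normalization, a fit of the compared groups only, no trend, the replicate block, and leaving out each library in turn. After seeing the data, further alternatives were added: all table entries, a correction for GC content and length in each library (loess, span 0.5), a Sertoli marker score (the mean log2 value of the 4 tested Sertoli markers) as a covariate, both also with the block, and leaving out 1 replicate number in all groups.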

Results

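Transcript levels were measured by RNA sequencing in undifferentiated spermatogonia of the mouse, the germ cell population that holds the stem cells of the testis. The cells were sorted at postnatal day 6 on EGFP driven by Id4, a gene for an inhibitor of DNA binding whose expression marks the stem cell end of this population. There were 3 libraries of all ID4-EGFP+ cells, 3 of the fraction that stained most strongly for the tetraspanin TSPAN8 (TSPAN8-high) and 3 of the fraction that stained weakly (TSPAN8-low). The absolute depth of the libraries is unknown, and their relative depth lay between 0.856 and 1.05 of that of all ID4-EGFP+ replicate 1. Between 10734 and 11155 table entries per library reached 1 FPKM, and within each group the libraries correlated across genes with Pearson's r of at least 0.986. Libraries of different groups were about as alike, with r of 0.982 to 0.994.

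Transcripts of the sorted protein and of the reporter gene followed the sort. Tspan8 stood at 34.0 ± 8.41 FPKM in TSPAN8-high, 15.2 ± 1.39 in all ID4-EGFP+ and 9.73 ± 2.71 in TSPAN8-low (SD, n = 3 each), a ratio of 3.50 between the fractions. Id4 stood at 67.2 ± 7.17, 35.6 ± 4.34 and 26.2 ± 8.14 FPKM in the same order, a ratio of 2.57. In limma both differed between the fractions (Tspan8 log2 fold change 1.72, SE 0.21, adjusted p = 0.00246; Id4 1.37, SE 0.21, adjusted p = 0.00567). Epha2, which encodes another surface protein used to sort these cells, was low and differed by 0.50 (adjusted p = 0.0440). Pvr, a further sorted surface protein, was under the minimum for testing, at 0.534 ± 0.0416 FPKM in TSPAN8-high and 0.420 ± 0.00751 in TSPAN8-low. For each of the 4 genes the values of the fractions did not overlap and the exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. The Epha2 call was lost without any 1 of the 9 libraries (adjusted p up to 0.161), and without replicate 2 of all groups the adjusted p was 0.0555 for Tspan8 and 0.101 for Id4.

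**Figure D1:**
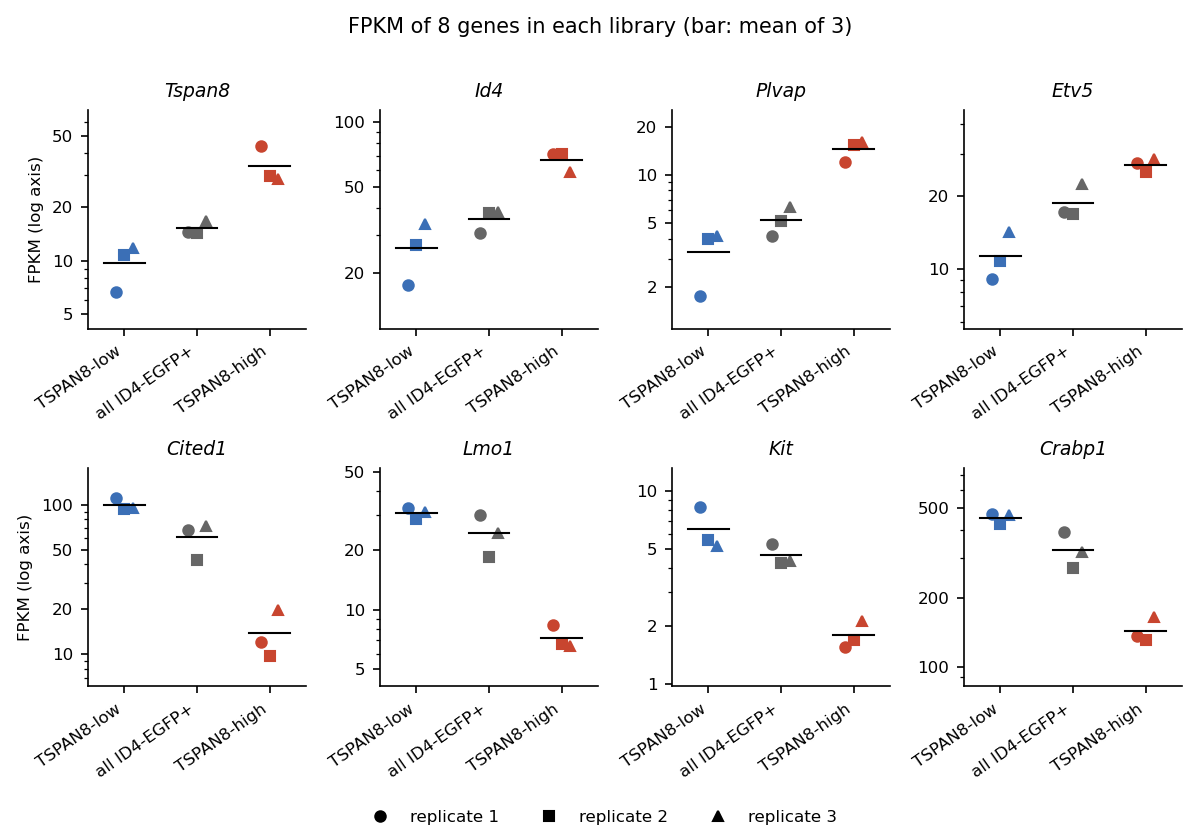
FPKM (log axis) of 8 named genes in each of the 9 libraries, with 1 symbol per replicate number and a bar at the mean of the 3 libraries of TSPAN8-low, all ID4-EGFP+ and TSPAN8-high. Tspan8, Id4, Plvap and Etv5 were higher and Cited1, Lmo1, Kit and Crabp1 lower in all 3 TSPAN8-high libraries than in all 3 TSPAN8-low libraries.

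The comparison of the fractions addressed how transcript levels differ between ID4-EGFP+ cells with much and with little surface TSPAN8. Of 11142 tested genes, 380 were higher and 239 lower in TSPAN8-high, and 97 and 85 of these differed by at least 2-fold. Among genes past the threshold whose 3 values per fraction did not overlap, the largest rise was in Plvap, which encodes a protein of membrane diaphragms (14.5 ± 2.14 FPKM against 3.30 ± 1.34, log2 fold change 1.89, SE 0.24, adjusted p = 0.00246). It was followed by Optn, an autophagy receptor gene (1.75, SE 0.22), Tspan8 itself, and Gfpt2, which encodes an enzyme of the hexosamine pathway (1.69, SE 0.29). Pqlc1, Oit1, the transferrin gene Trf, Rab4a, whose product acts in endosome recycling, the beta-defensin gene Defb41 and Cbln2 rose by 1.6 to 1.68 (adjusted p from 0.00116 to 0.0108). Among the same genes the largest fall was in Cited1, which encodes a transcriptional coregulator (13.9 ± 5.32 FPKM against 99.8 ± 9.43, log2 fold change -2.81, SE 0.25, adjusted p = 0.000650). Gchfr, a regulator of tetrahydrobiopterin synthesis, fell by 2.36, Ly6k by 2.24, the neuropeptide gene Gal by 2.06 and the transcriptional regulator gene Lmo1 by 1.97 on the log2 scale (SE 0.18 to 0.24). Crabp1, which encodes a retinoic acid binding protein, fell from 454 ± 24.4 to 144 ± 18.7 FPKM (log2 fold change -1.65, SE 0.16). Tbx1, Lhx8, Tcea3 and Gnai1 fell by 1.5 to 1.56.

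By limma, 2448 genes had an unadjusted p under 0.05. With the replicate block 2131 genes passed (1313 higher, 818 lower), among them all 619 called without it. The split between higher and lower calls depended on the scaling: it was 223 to 310 with the authors' normalized values, 219 to 369 with a common median and 250 to 300 after quantile normalization, against 380 to 239. With the block it was 926 to 1018, 799 to 1229 and 961 to 1010, against 1313 to 818. The count fell to 185 without TSPAN8-high replicate 2, 284 without TSPAN8-high replicate 3, 364 without TSPAN8-low replicate 1, 288 without TSPAN8-low replicate 2. It fell to 372, 10 and 90 without replicate 1, 2 or 3 of all groups, and it was 296 with a Sertoli marker score as a covariate and 2 with this score and the block. This score was higher in TSPAN8-high than in TSPAN8-low within each replicate number. With the block, adding it raised the median SE over all tested genes from 0.135 to 0.295. The fall to 2 therefore does not measure a share from Sertoli RNA. With the block the count fell to 1181, 1219 and 1053 without TSPAN8-high replicates 1, 2 and 3, 1295 and 1296 without TSPAN8-low replicates 2 and 3, and 1152 and 779 without replicate 2 or 3 of all groups. Of the 48 named genes that passed, 33 did so without each of the 9 libraries in turn; of the 20 with the largest changes, the Gnai1 call alone was lost, without TSPAN8-high replicate 3 (adjusted p = 0.0710).

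Genes of spermatogonial stem cells and of their response to the niche factor GDNF were higher in TSPAN8-high as a group. Of 16 tested members of the stem cell list, 14 rose and 0 fell, with the same count adjusted over the list alone and a median log2 fold change of 1.19 (2.28-fold). Foxc2, a forkhead transcription factor gene, rose from 2.08 ± 0.190 to 6.74 ± 0.766 FPKM (log2 fold change 1.32, SE 0.15, adjusted p = 0.00143). The T-box gene T (brachyury) rose from 0.406 ± 0.104 to 2.29 ± 0.251 FPKM (1.23, SE 0.15, adjusted p = 0.00246) and Etv5, an ETS factor gene induced by GDNF, from 11.3 ± 2.68 to 27.1 ± 1.75 FPKM (1.21, SE 0.18, adjusted p = 0.00500). The other members were named after their values were seen. Gfra1 and Ret, whose products form the GDNF receptor, rose by 1.35 and 1.13, and Nanos2, Tcl1, Egr2, Bcl6b, Lhx1, Eomes and Cxcr4 by 0.77 to 1.27. Egr4 (0.19, adjusted p = 0.681) and Mycn (-0.10, adjusted p = 0.781) did not pass. The list passed camera at adjusted p = 1.56e-13, and had adjusted p = 0.210 with an estimated correlation. RNA of Sertoli cell markers was also more abundant in TSPAN8-high within each replicate number. Clu stood at 34.6 ± 22.6 FPKM against 12.5 ± 16.6 in TSPAN8-low. By camera the list of these markers did not pass (adjusted p = 0.0690), though it did with the block. The wider undifferentiated list did not pass (median log2 fold change 0.26, adjusted p = 0.121, 0.302 with an estimated correlation); Cdh1, for E-cadherin, alone of its 15 members rose (0.73, adjusted p = 0.0496), and 5 rose when adjusted over the list alone (with the block 6 rose, and adjusted over the list alone 6 rose and 1 fell). Of its other members, Zbtb16 had 0.59 (adjusted p = 0.0567), Dppa4 0.70 (0.0942) and Itga6 0.47 (0.0826), and with the block all 3 passed (adjusted p from 0.00648 to 0.0314). The Cdh1 call was lost without any of 8 of the 9 libraries (adjusted p up to 0.136); the wider list passed without a filter (adjusted p = 0.0429) and without replicate 3 of all groups (0.0494).

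The lists of progenitor and differentiating genes were lower in TSPAN8-high by camera at the preset correlation, and neither passed with an estimated one. Of 10 tested members of the differentiating list, 6 fell and 0 rose (7 fell adjusted over the list alone, where with the block 9 fell and 1 rose), with a median of -0.77. Kit, which encodes the stem cell factor receptor, fell from 6.35 ± 1.67 to 1.79 ± 0.293 FPKM (log2 fold change -1.38, SE 0.18, adjusted p = 0.00264). Stra8, a gene induced by retinoic acid before meiosis, fell from 187 ± 13.9 to 90.9 ± 13.7 FPKM (-1.04, SE 0.15, adjusted p = 0.00382), and Dmrtb1 fell by 1.23 (adjusted p = 0.00154). The list passed camera at adjusted p = 5.51e-09, with adjusted p = 0.0830 with an estimated correlation. In the same contrast the Sertoli markers had a median log2 fold change of 1.71. Their list did not pass by camera (adjusted p = 0.0690), though it did with the block. Of 8 progenitor genes, Crabp1 and Sohlh1, a transcription factor gene of early differentiation (-0.69, adjusted p = 0.0195), fell and 0 rose, also adjusted over the list alone. Neurog3 (-0.68, adjusted p = 0.165) and Sox3 (-0.43, adjusted p = 0.202) did not pass; with the block Neurog3 did (0.0111). The progenitor list passed at adjusted p = 0.00521 (0.242 with an estimated correlation, 0.261 with the block and a Sertoli marker score). Of 14 meiosis genes, Sycp3, for a component of the synaptonemal complex, fell (-0.94, adjusted p = 0.0400) and the list did not pass (adjusted p = 0.156, 2 lower adjusted over the list alone). Syce2 (-0.51), Prdm9 (-0.47) and Rec8 (0.52) had adjusted p of 0.0805, 0.207 and 0.229, and Syce2 and Rec8 passed with the block (0.0119 and 0.0361), which gave 1 higher and 2 lower, also adjusted over the list alone. The Sohlh1 call was lost without TSPAN8-high replicate 2 or 3 or TSPAN8-low replicate 1 (adjusted p up to 0.0854). The Sycp3 call was lost without all ID4-EGFP+ replicate 3, TSPAN8-high replicate 2 or 3, or TSPAN8-low replicate 1 or 2 (adjusted p up to 0.142).

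Feedback genes of receptor tyrosine kinase signalling, cell cycle genes and glycolytic genes were higher in TSPAN8-high as lists, by camera at the preset correlation. Of 10 splits of the same libraries, the real one included, 3 gave at least the real count of 8 lists. The number of list calls between the fractions therefore does not set the real grouping apart. Of 8 tested growth factor response genes, Dusp6, for an ERK phosphatase, rose from 28.4 ± 7.47 to 70.8 ± 3.91 FPKM (1.31, SE 0.19, adjusted p = 0.00495), and the Sprouty genes Spry1 (0.95, adjusted p = 0.0201) and Spry4 (0.91, adjusted p = 0.0262) also rose. The count was 5 adjusted over the list alone (with the block 5 higher and 1 lower, also over the list alone), Dusp5 had 0.63 (adjusted p = 0.0579, 0.0164 with the block), and the list passed at adjusted p = 0.00233 (0.242 with an estimated correlation). Of the 22 cell cycle genes 0 passed by limma, also adjusted over the list alone, and 3 had an unadjusted p under 0.05 (with the block 5 rose, and 9 adjusted over the list alone). Their estimates lay above 0 for 20 of 22, with Top2a at 0.72 (adjusted p = 0.0823), Cdc20 at 0.58 (0.149), Mcm3 at 0.52 (0.256) and Mki67 at 0.47 (0.0606), all 4 past the threshold with the block (0.0124 to 0.0203). The list passed at adjusted p = 0.0131 with a median of 0.30 (0.261 with an estimated correlation). Of 15 glycolytic genes, Ldha, for lactate dehydrogenase A, rose (0.84, adjusted p = 0.0304), also adjusted over the list alone, 8 rose with the block (9 over the list alone), and the list passed at adjusted p = 0.0172 (0.524 with an estimated correlation). Aldoc (0.51), Pfkp (0.70) and Slc2a1 (0.39) had adjusted p of 0.144 to 0.179 and passed with the block (0.00778 to 0.0421). In the same libraries the Sertoli marker Cst12 stood at 25.9 ± 16.3 FPKM against 9.88 ± 12.4, which did not pass by limma without the block and did with it. The calls of Spry1, Spry4 and Ldha were each lost without TSPAN8-high replicate 2 or 3 or TSPAN8-low replicate 1 or 2 (adjusted p up to 0.113). The cell cycle list was lost without TSPAN8-high replicate 3 (0.0511), and the glycolysis list without TSPAN8-high replicate 2 (0.0574) or 3 (0.132), TSPAN8-low replicate 1 (0.154) or replicate 3 of all groups (0.0609). With the Sertoli score as a covariate the cell cycle and glycolysis lists did not pass (adjusted p = 0.0914 and 0.387). With this score and the block the growth factor response and cell cycle lists did not pass (0.146 and 0.0678).

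Immediate-early and heat-shock genes, which respond to cell handling, and adhesion and matrix genes were also higher as lists. Of 12 immediate-early genes, Junb rose (0.69, adjusted p = 0.0411) and 0 fell; 8 rose adjusted over the list alone, and the list passed at adjusted p = 0.00348 (0.261 with an estimated correlation). Ier2 (0.82), Ier3 (0.78) and Dusp1 (0.46) had adjusted p of 0.0843, 0.104 and 0.0807 and passed with the block, where 8 members rose. Of 8 adhesion and matrix genes, the integrin gene Itgb5 rose (0.88, adjusted p = 0.0394), 2 rose adjusted over the list alone (3 and 5 with the block), and the list passed at adjusted p = 0.0351 (0.325 with an estimated correlation). In the same contrast the Sertoli markers had a median of 1.71, while their list did not pass by camera without the block (adjusted p = 0.0690). Sparc, a matrix protein gene also expressed by Sertoli and stromal cells, stood at 7.75 ± 6.88 FPKM against 2.09 ± 2.57 (1.47, adjusted p = 0.247, 0.000636 with the block), Itga1 at 0.51 (adjusted p = 0.104, 0.0488 with the block) and Mmp2 at 0.32 (adjusted p = 0.190). Junb was lost without any of 6 libraries, TSPAN8-high and TSPAN8-low, and Itgb5 without TSPAN8-high replicate 2 or 3 or TSPAN8-low replicate 1 or 2 (adjusted p up to 0.137). The adhesion list did not pass with the authors' normalized values (adjusted p = 0.0553), nor without TSPAN8-high replicate 3 (0.0770), TSPAN8-low replicate 1 (0.0852) or 2 (0.0777) or replicate 2 of all groups (0.107). Nor did it pass with the Sertoli score (0.251) or this score and the block (0.261).

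**Figure D2:**
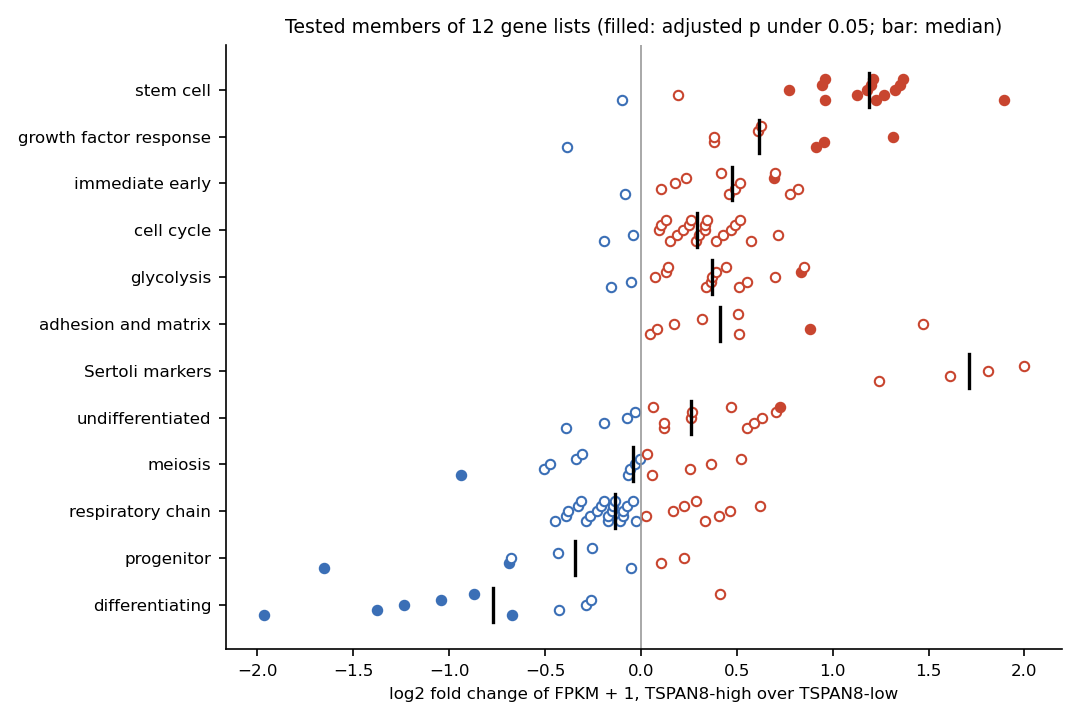
Log2 fold change of FPKM + 1, TSPAN8-high over TSPAN8-low, of each tested member of 12 gene lists, 1 point per gene, with a bar at the list's median and filled points for genes with an adjusted p under 0.05. The stem cell list had its median at 1.19 with 14 of 16 members filled, and the differentiating list at -0.77 with 6 of 10.

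The remaining lists of germ cell genes did not pass. Among 29 respiratory chain genes 0 passed by limma, also adjusted over the list alone (3 with an unadjusted p under 0.05), and the list had adjusted p = 0.0948 (0.524 with an estimated correlation) and a median of -0.13; Ndufv1 had 0.62 (adjusted p = 0.0932, 0.00347 with the block), and Ndufv2, Cycs and Cox5b -0.31 to -0.45 (adjusted p from 0.197 to 0.245; Cycs 0.0497 with the block). With the block 2 rose and 1 fell (1 and 0 over the list alone). The list passed, lower, without TSPAN8-low replicate 1 (adjusted p = 0.00624) and with the Sertoli score (0.00761), though not with this score and the block (0.811). Of 8 DNA methylation genes, Gadd45b, a stress-induced gene (-0.90, adjusted p = 0.00994), and Tet3, for a 5-methylcytosine dioxygenase (-0.65, adjusted p = 0.0243), fell, 2 also adjusted over the list alone (with the block also 1 higher there), while Uhrf1 (0.43) and Gadd45a (-0.31) did not pass (list adjusted p = 0.156 on the lower side, with a median just above 0 and a mean of -0.14). Of 17 other tetraspanins, Cd82 rose (0.90, adjusted p = 0.0320) and Cd63, a late endosome marker, fell from 233 ± 1.56 to 91.4 ± 8.14 FPKM (-1.34, SE 0.13, adjusted p = 0.000674); adjusted over the list alone 1 rose and 2 fell (list adjusted p = 0.262; with the block 1 rose and 3 fell). Tspan4 (-0.43) and Tspan13 (-0.65) had adjusted p of 0.0737 and 0.152 and passed with the block (0.0206 and 0.0118). Of the retinoic acid genes, Rxrg, for a retinoid X receptor, rose (0.66, adjusted p = 0.0466), and the list of 12 did not pass (adjusted p = 0.680 on the lower side, with a median just under 0 and a mean of 0.06), with 2 higher adjusted over the list alone and 3 higher with the block. Dhrs3 (0.56) and Aldh1a1 (1.16) passed with the block only (0.0223 and 0.00230). Of 10 BMP and Id genes 0 passed by limma, also adjusted over the list alone (4 with an unadjusted p under 0.05, list adjusted p = 0.813), with Smad6 at 0.57 (adjusted p = 0.0690, 0.0284 with the block, the 1 gene that then passed), Smad7 at 0.36, Id1 at -0.62 and Id2 at -0.80. Of 5 Eph and ephrin genes 0 passed by limma (2 with an unadjusted p under 0.05; list adjusted p = 0.247; 1 higher and 1 lower adjusted over the list alone); Ephb1 had 0.47 (adjusted p = 0.109, 0.0408 with the block, which gave 1 higher over all genes and 1 higher and 2 lower over the list alone), Efna1 -0.48, Efna3 -0.34 and Efna2 -0.26. Calls lost without at least 1 library were Cd82 (5 libraries, adjusted p up to 0.103), Rxrg (8, up to 0.161), Tet3 (3, up to 0.0887) and Gadd45b (TSPAN8-high replicate 2, 0.0528).

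Transcripts that mark other testis cell types were present in the libraries, although the sort on EGFP would remove cells without the reporter. The 4 tested Sertoli markers were Clu, Cst12, Inha and Aard. Within each replicate number they were higher in TSPAN8-high than in TSPAN8-low. Clu stood at 19.1, 24.2 and 60.6 FPKM in TSPAN8-high replicates 1 to 3, at 2.38, 3.45 and 31.6 in TSPAN8-low and at 2.49, 15.3 and 26.4 in all ID4-EGFP+. Without the block 0 of the 4 passed by limma (log2 fold changes 1.24 to 2.00, adjusted p from 0.191 to 0.313; 0 adjusted over the list alone; 3 with an unadjusted p under 0.05), and with the block all 4 rose, also adjusted over the list alone (0.00109 to 0.00584). The Sertoli list had adjusted p = 0.0690 without the block and 0.00108 with it (0.442 and 0.306 with an estimated correlation). It passed with the authors' normalized values (0.0408), a common median (0.0225) and quantile normalization (0.0465). It also passed without a filter (0.0404), in a fit of the 2 groups (0.0317), without all ID4-EGFP+ replicate 1 (0.0334) or 3 (0.0354), TSPAN8-high replicate 2 (0.0314), TSPAN8-low replicate 3 (0.000950) or replicate 3 of all groups (8.88e-06). Amh and Sox9, also Sertoli markers, reached at most 0.714 and 0.197 FPKM in any library. The Sertoli score thus rests on 4 of the 14 list members with values. Whether RNA of these 4 came from Sertoli cells was not tested. Of 3 leukocyte markers, the macrophage gene Mrc1 rose to 1.37 ± 0.223 from 0.322 ± 0.1 FPKM (adjusted p = 0.00828), also adjusted over the list alone; Cd68 had 0.59 (adjusted p = 0.192, 0.0384 with the block, where 2 of the 3 rose) and Cd14 -0.28, and the list did not pass (adjusted p = 0.174, 0.445 with an estimated correlation) except without a filter (0.000431). The untested macrophage genes Lyz2, C1qb and Tyrobp reached 7.95, 6.28 and 7.04 FPKM in TSPAN8-high replicate 3 and 0.989, 1.92 and 3.41 in replicate 2, and were under 1 in the other 7 libraries. Myl9, Tagln and Acta2 of the peritubular myoid markers had 0.87 (adjusted p = 0.0518, 0.00232 with the block), 0.42 and 0.65, with 1 higher adjusted over the list alone (list adjusted p = 0.0868, 0.423 with an estimated correlation); 0 passed over all genes by limma, and 2 had an unadjusted p under 0.05 (with the block 1 and, over the list alone, 2 rose). This list passed, higher, without TSPAN8-high replicate 2 (0.0381), TSPAN8-low replicate 3 (0.0258), or replicate 2 (0.0476) or 3 (0.0459) of all groups. Of the interstitial markers, Pdgfra had 0.62 (adjusted p = 0.0535, 0.0180 with the block) and Dcn 1.03, with 1 higher adjusted over the list alone (list adjusted p = 0.156, 0.359 with an estimated correlation, and 0.0459 without replicate 3 of all groups). The endothelial markers Flt1 (0.39) and Egfl7 (0.03) did not pass (list adjusted p = 0.416; with the block 1 higher adjusted over the list alone). No Leydig or red blood cell marker reached the minimum for testing, with Insl3 highest at 4.82 FPKM in TSPAN8-low replicate 3 and Hba-a1 at 16.7 in TSPAN8-high replicate 3.

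**Figure D3:**
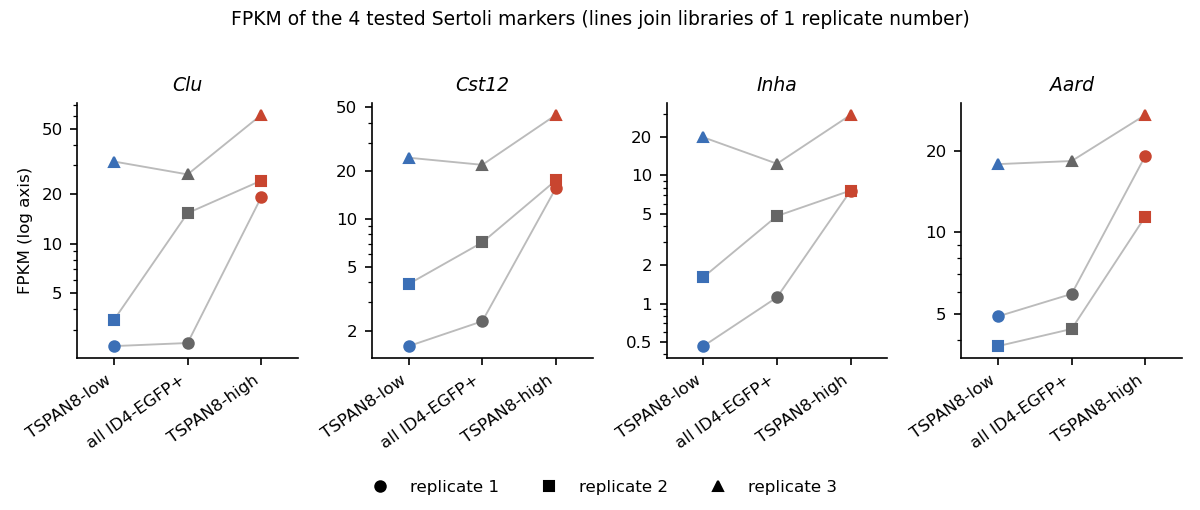
FPKM (log axis) of the Sertoli markers Clu, Cst12, Inha and Aard in each library of TSPAN8-low, all ID4-EGFP+ and TSPAN8-high, with lines joining libraries of 1 replicate number. Within each number TSPAN8-high lay above TSPAN8-low, and TSPAN8-low replicate 3 (Clu 31.6 FPKM) lay above TSPAN8-high replicates 1 and 2 (19.1 and 24.2) for Clu, Cst12 and Inha.

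Each fraction was also compared with the population it was drawn from. The fractions were stained and sorted again, while all ID4-EGFP+ cells were taken as a whole. In any contrast with all ID4-EGFP+ by itself, TSPAN8 level therefore cannot be told apart from this added handling. Against all ID4-EGFP+, TSPAN8-high had 3 genes higher and 13 lower. The lower ones were led by Cited1 (log2 fold change -2.08, SE 0.25, adjusted p = 0.0123), Lrrn4cl (-1.72, SE 0.24, adjusted p = 0.0298), Gchfr (-1.61, SE 0.24, adjusted p = 0.0350), Lmo1 (-1.61, SE 0.18, adjusted p = 0.0116) and Ctcfl, a germline paralogue of the insulator protein CTCF (33.7 ± 7.14 to 11.5 ± 3.65 FPKM; -1.49, SE 0.25, adjusted p = 0.0448). The higher ones were the small nucleolar RNA gene Snora28 (100 ± 44.4 to 462 ± 120 FPKM; 2.28, SE 0.38), Slxl1 (1.01, SE 0.17) and Ppfibp2 (0.95, SE 0.15), each at adjusted p = 0.0448. By camera 5 lists passed at the preset correlation and 0 with an estimated one, where the adjusted p was 0.227 (stem cell), 0.146 (progenitor), 0.0842 (differentiating), 0.28 (immediate early) and 0.316 (Sertoli). Stem cell genes were higher (median 0.53, 0 past over all genes by limma, 12 with an unadjusted p under 0.05, 11 adjusted over the list alone, adjusted p = 1.49e-10), and progenitor (1 lower, 5 adjusted over the list alone, 0.000169) and differentiating genes (median -0.46, 2 lower, 6 adjusted over the list alone, 6.20e-09) were lower. Immediate-early genes (adjusted p = 0.0112) and Sertoli markers (0.0229; 1.83e-05 with the block) were higher, each with 0 members past the threshold by limma, also adjusted over the list alone (2 and 0 with an unadjusted p under 0.05). With the block 4 stem cell genes (Plvap, T, Id4 and Egr2) and 2 Sertoli markers rose, and 3 progenitor and 4 differentiating genes fell; over the list alone 4 Sertoli markers and 3 immediate-early genes rose. The fold changes followed GC content across genes (Spearman's rho -0.32; genes are not independent replicates). By limma 1085 genes had an unadjusted p under 0.05, and with the block 344 genes passed (137 higher, 207 lower), including all 16. With the block the adhesion and matrix (adjusted p = 0.0482) and peritubular myoid lists (0.0499) were higher (0.215 and 0.325 with an estimated correlation). Tspan8 (1.09, adjusted p = 0.0719, 0.0138 with the block) and Id4 (0.90, adjusted p = 0.0875, 0.0153 with the block) passed with the block only. The count of 16 was 0 without all ID4-EGFP+ replicate 1 or 3, 1, 3 and 66 without TSPAN8-high replicate 1, 2 or 3, 111, 6 and 10 without TSPAN8-low replicate 1, 2 or 3, 0, 6 and 0 without replicate 1, 2 or 3 of all groups. It was 0 without a filter, 7 with the authors' normalized values and 27 in a fit of these groups only. The blocked count was 90, 548 and 94 without all ID4-EGFP+ replicate 1, 2 or 3, 101, 165 and 202 without TSPAN8-high replicate 1, 2 or 3, 598 without TSPAN8-low replicate 1, and 92 and 87 without replicate 1 or 3 of all groups.

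TSPAN8-low was compared with all ID4-EGFP+ in the same way. By limma 0 genes passed (910 with an unadjusted p under 0.05), and with the block 5 did. These were named after their values were seen: Snora28 was higher (log2 fold change 1.28, adjusted p = 0.0352 with the block), and Optn (-1.10, 0.00551), Gfpt2 (-1.05, 0.0217), Jdp2 (-0.88, 0.0352) and the small Cajal body RNA gene Scarna13 (-1.67, 0.0352) were lower. Over all genes 0 members of any list passed. By camera 3 lists passed at the preset correlation and 0 with an estimated one, where all 3 had adjusted p = 0.260. Stem cell genes were lower as a list (median -0.51, 9 with an unadjusted p under 0.05, 6 adjusted over the list alone, adjusted p = 8.21e-10), as were growth factor response genes (median -0.49, 6 with an unadjusted p under 0.05, 6 adjusted over the list alone, 0.000763), and differentiating genes were higher (median 0.24, 2 with an unadjusted p under 0.05, 0 adjusted over the list alone, 0.000763). With the block 13 stem cell genes were lower adjusted over the list alone. The fold changes followed GC content across genes here too (Spearman's rho -0.37). With the block, meiosis genes were also higher (0.0324), and cell cycle (0.0331) and glycolysis genes (0.00550) lower (0.322, 0.522 and 0.487 with an estimated correlation). The count of 0 became 1 without replicate 2 or without replicate 3 of all groups.

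The mean of both fractions was also set against all ID4-EGFP+. It averages the fractions, so a call does not show that both differed alike. Cells stained between the fractions are not part of this mean. By limma 0 genes passed (377 with an unadjusted p under 0.05). With the block Snora28 was higher (1.78, adjusted p = 0.00114) and Lrrn4cl lower (-0.98, adjusted p = 0.0482). Progenitor (median -0.29, 2 with an unadjusted p under 0.05, 0 adjusted over the list alone, 3 with the block) and differentiating genes (median -0.18, 1 lower adjusted over the list alone) were lower as lists, both at adjusted p = 0.0160 and 0.420 with an estimated correlation, and Sertoli markers were higher with the block (0.00762, and 0.521 with an estimated correlation). The fractions did not shift alike in these lists. In TSPAN8-low by itself the differentiating list was higher than in all ID4-EGFP+ (9 of 10 above 0, median 0.24, adjusted p = 0.000763 at the preset correlation). The progenitor list did not pass there (median -0.09, adjusted p = 0.810 on the higher side), and the Sertoli markers had a median of -0.33, against 1.35 in TSPAN8-high. Lrrn4cl had -0.25 in TSPAN8-low and -1.72 in TSPAN8-high, while Snora28 was higher in both (1.28 and 2.28). In this contrast the fold changes followed GC content across genes (Spearman's rho -0.50; genes are not independent replicates), against 0.03 between the fractions. The count of 0 became 3 without replicate 2 and 1 without replicate 3 of all groups.

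The genes that differed between the fractions were also placed by their level in the unfractionated cells. They were chosen for a gap between the fractions, which favours a mean between them, so the shares are given without a test. Of the 619 genes, 553 (89.3%) had their all ID4-EGFP+ mean between the means of the fractions: 367 of the 380 higher in TSPAN8-high and 186 of the 239 lower. Of the others, the 53 lower genes were above both fractions in all ID4-EGFP+, and of the higher genes 4 were above and 9 below both.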

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

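All tests with a Sertoli marker score, with a correction for GC content and length, with all table entries or without 1 replicate number in all groups were chosen after the data were seen. Between the fractions, no gene taken by the naming rule that passed by limma, and no list that passed, reversed its direction under the alternatives run. Of the named genes that did not pass, several changed sign, such as Dcn (1.03, and -0.13 without replicate 2 of all groups) and Egfl7 (0.03, and -0.06 without TSPAN8-high replicate 3). Clu (2.00) and Inha (1.61), which passed with the block and are part of the Sertoli score, had -0.23 and -0.36 with both. Itga1 (0.51) and Cd68 (0.59), which also passed with the block, had -0.12 and -0.10 with both. Outside that rule, Cxcr4, which passed between the fractions (0.77), had -0.03 with the block and the Sertoli score, and Defb19, which passed with the block (1.47), had -0.54 with the score (SE 0.54). Of the 48 named genes that passed between the fractions, 46 kept their call with a pseudocount of 0.1, 41 with the authors' normalized values, 40 with a common median, 40 with quantile normalization, 34 without a filter, 48 with the replicate block, 33 with the Sertoli score, 0 with the block and the score, and 35, 8 and 27 without replicate 1, 2 or 3 of all groups. The count of genes between TSPAN8-high and TSPAN8-low (619) was 293 without a filter, where more genes were tested, 2131 with the replicate block, 2221 with the block and the GC correction, 296 with the Sertoli score and 2 with the block and the score. Against all ID4-EGFP+, the count of TSPAN8-high (16) was 0 without a filter, 7 with the authors' normalized values, 27 with only the compared groups, 344 with the replicate block, 325 with the block and the GC correction, 95 with the Sertoli score and 2 with the block and the score. That of TSPAN8-low (0) was 5, 1 and 2 with the replicate block, the block and the GC correction, and the block and the score. That of the mean of both fractions (0) was 2, 1 and 1 in the same order, and 3 with all entries. The blocked count of TSPAN8-high against TSPAN8-low was 1026 without a filter and 2 with the score, and that of TSPAN8-high against all ID4-EGFP+ was 0 without a filter, 914 with only the compared groups and 2 with the score. The count of lists between the fractions (8) was 6 with the Sertoli score, where the cell cycle, glycolysis, and adhesion and matrix lists did not pass and the respiratory chain list did. It was 4 with the block and the score, where the progenitor, growth factor response, cell cycle, and adhesion and matrix lists did not pass, and 0 with an estimated correlation, with or without the block. The count of list calls against all ID4-EGFP+, summed over contrasts (10), was 19 without a filter, 16 with the block, 6 with the Sertoli score and 0 with an estimated correlation, with or without the block. With the block and the score, Tspan8 had a log2 fold change of 0.97 (adjusted p = 0.399) and Id4 of 0.59 (adjusted p = 0.470). In that fit the median SE over all tested genes was 0.295, against 0.135 with the block only. Calls lost there do not measure a share from Sertoli RNA, since the score followed the sort. Without 1 library or 1 replicate number the counts ranged from 10 (without replicate 2 of all groups) to 633 between the fractions, 0 to 111 for TSPAN8-high and 0 to 1 for TSPAN8-low against all ID4-EGFP+, 0 to 3 for the mean, 779 to 2325 and 87 to 598 for the blocked counts, 5 (without TSPAN8-high replicate 3) to 11 (without replicate 3 of all groups) for the lists between the fractions and 9 (without all ID4-EGFP+ replicate 1) to 21 (without all ID4-EGFP+ replicate 3; 18 without TSPAN8-high replicate 1 or TSPAN8-low replicate 1) for the lists against all ID4-EGFP+. Tspan8 ranged from 1.30 to 1.96 and Id4 from 1.08 to 1.66. Where libraries were left out, fewer samples were tested; for the other settings the cause was not tested. Beyond the calls and counts given here and beside the results, the block changed no other call of a named gene between the fractions or of a list, except Snora28 (log2 fold change 1.00 between the fractions, adjusted p = 0.15, 0.00367 with the block). Absolute depth is unknown, so no floor can be given for genes with low FPKM, and changes under 2-fold were often not detectable.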

Other observations

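The test of gene families by symbol, the tests of GC content and length on the stem cell, Defb and histone genes, the S phase test and the tests on parts of the Defb family were chosen after the results were seen, as were all uses of the Sertoli score as an alternative.

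Beyond the lists, 311 families of genes sharing a symbol stem were tested between TSPAN8-high and TSPAN8-low with camera, and 6 passed (0 with an estimated correlation, adjusted p = 0.954 for each). Of 10 splits of the same libraries, the real one included, 6 gave at least 6 families, and the highest other gave 24. The number of families therefore does not set the real grouping apart, and the family calls below carry this limit. Histone (Hist) genes were lower, with 43 of 53 below 0 and a median log2 fold change of -0.27 (adjusted p = 0.00033, 1.09e-05 with the block). Of these, Hist1h2ba, which encodes a testis histone H2B, fell from 12.2 ± 2.29 to 5.27 ± 1.24 FPKM (-1.08, adjusted p = 0.0103) and Hist1h2bj fell by 0.90 (adjusted p = 0.0330), while with the block 19 fell. Reads of histone copies can be shared, and poly(A) priming reads replication histone mRNA poorly, so their levels are uncertain. Beta-defensin (Defb) genes, which encode small secreted peptides, were higher (7 of 7 above 0, median 1.20, adjusted p = 0.00934): Defb41, Defb47 and Defb20 rose by 1.20 to 1.61, and Defb19 and Defb36 also rose with the block. Dynein (Dync) motor genes were higher (7 of 7 above 0, median 0.50, adjusted p = 0.0239; 0.0379 with the block, but 0.0622 with the block after quantile normalization), with Dync1i1 at 0.99 (adjusted p = 0.00862) and Dync1i2 at 0.71 (adjusted p = 0.0274), and 4 rose with the block. Mitochondrial ribosome (Mrpl, median -0.16, adjusted p = 0.00966), complex I (Ndufa, -0.23, 0.0240) and Smim genes (-0.31, 0.0265) were lower, with 0 members past the threshold by limma and 4, 4 and 2 with the block, but did not pass with the authors' normalized values (0.199, 0.307 and 0.0730) or quantile normalization (0.243, 0.279 and 0.0846), except the Smim genes with the block and the authors' normalized values (0.0495). None of the 6 changed direction under the scalings run.

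The stem cell genes were higher in TSPAN8-high. Sertoli marker RNA was also more abundant there within each replicate number, with calls of single markers by limma in the fit with the block only. The sort on EGFP would remove cells without the reporter, and how such RNA passed it was not tested. With the Sertoli score as a covariate their median log2 fold change was 0.935 (quartiles 0.709 to 1.10), against 1.19 without it, and the list passed at adjusted p = 1.05e-10; with the block and the score it was 0.674, with the median SE growing from 0.159 to 0.326, and the list passed at 1.76e-05, both at the preset correlation (with an estimated one, and no score, the list had 0.210, and 0.2 with the block). TSPAN8-low replicate 3, with more Clu RNA than TSPAN8-high replicates 1 and 2, lay below both for 14 of 16 stem cell genes, though 1 library by itself excludes nothing. After a correction for GC content and length the median was 1.12 (adjusted p = 8.12e-13). Across genes, fold changes between the fractions barely followed GC content or length (Spearman's rho 0.03 and 0.05). The correction therefore had little to remove between them, and the call after it adds little. If Sertoli RNA were the whole source and the score captured all of it, the list would not have stayed past the threshold. The score rests on 4 markers, however, so Sertoli RNA that it misses could remain in these values. They therefore do not decide on Sertoli RNA as the whole source. The weak GC trend argues against GC content as the whole source. The score was higher in TSPAN8-high within each replicate number, so the fall of the median with it does not measure a share from Sertoli RNA. Tspan8, the sorted gene itself, also fell with the block and the score, from 1.72 to 0.97. A difference between the germ cells of the fractions is a hypothesis that was found and tested on the same data.

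With the Sertoli score as a covariate the median of the Defb genes fell from 1.20 to 0.55 (quartiles 0.322 to 1.29) and the family call ended (adjusted p = 0.0594). For Defb41, Defb47 and Defb20 the median was 1.32 with the score (1.52 without it) but 0.564 with the block and the score (median SE 0.426), and for Defb19 and Defb36 it was -0.107 (1.29 without it) but 1.27 with both (median SE 0.53). TSPAN8-low replicate 3 lay below TSPAN8-high replicates 1 and 2 for 5 of 7 Defb genes, but not for Defb19 and Defb36. Here too 1 library excludes nothing. Across the 9 libraries Defb19 and Defb36 followed the score most closely of the 7 (r of 0.91 and 0.86). For Defb41, Defb47 and Defb20 r was 0.41, 0.35 and 0.65. The fits with and without the block point opposite ways. They therefore cannot tell Sertoli RNA that passed the sort on EGFP from a change in germ cells, for either part. The family passed after the GC and length correction at the preset correlation (adjusted p = 0.00364), but that correction had little to remove between the fractions. A GC trend is argued against because the fold changes between the fractions barely followed GC content (Spearman's rho 0.03).

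For the histone genes, 3 technical or cell cycle explanations were tested. At the preset correlation the family still passed after the GC and length correction with the block (adjusted p = 0.000675) and with 1 gene kept per set of near-identical profiles, 45 of 53 (adjusted p = 0.00124). Between the fractions, fold changes barely followed GC content (Spearman's rho 0.03), so the correction had little to remove. Only profiles correlated above 0.99 were joined. Copies that share a smaller part of their reads stay in, so that test cannot decide on shared reads. Fewer cells in S phase would lower replication genes, but Mcm2 to Mcm6, Pcna and Rrm2 had a median of 0.261 (quartiles 0.148 to 0.37). None of them passed by limma without the block (adjusted p from 0.256 to 0.904), and Pcna had -0.04. As a set they showed no fall. Their SEs (0.143 to 0.273) were about as large as the median, so they do not decide on fewer cells in S phase. The weak GC trend argues against GC content as the whole cause, and shared reads stay open. A difference between the fractions in histone transcripts that carry poly(A) tails is a hypothesis that was not tested.

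Other splits of the same libraries were run for each count. For TSPAN8-high against TSPAN8-low 1 of 10 splits gave 619 genes, the real one, and the highest other gave 1; among the 4 splits that part all pairs the real one gave 2131 with the block and the highest other 1. For TSPAN8-high against all ID4-EGFP+ it was 1 of 10, 16 genes against 1 (344 against 0 with the block). For TSPAN8-low against all ID4-EGFP+ the real count was 0, so that 10 of 10 splits reach it by construction and nothing follows; the highest gave 3 (with the block 5 against 2). For the lists 3 of 10 splits gave at least 8, the highest other 9, and for the families 6 of 10 gave at least 6, the highest other 24. Neither number sets the real grouping apart, and the list calls carry this limit as the family calls do. With 10 splits no share under 0.05 can be reached. For the mean of both fractions, the real count was also 0, so that 100 of 100 drawn splits reach it by construction and nothing follows about chance. Each of these splits set 1 group of 3 libraries against the mean of 2 other groups. A count therefore also depends on how the other libraries were divided. The highest gave 407, with all ID4-EGFP+ replicate 2 and TSPAN8-high replicates 2 and 3 as the group set against the others. The next gave 277, with the 3 TSPAN8-high libraries as that group. Such counts point to a structure of the samples, of which the difference of TSPAN8-high from the others may be a part. What set these splits apart was not tested.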
